A study of Mus musculus with 4 samples.

How the data were processed

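Total RNA from marginal zone macrophages sorted by flow cytometry was extracted with Trizol and converted to biotin-labelled cRNA with an Ambion MessageAmp kit, per the labels' protocols, and hybridised to Illumina single-colour mouse arrays. The submitters' processing notes name GenomeStudio 2011.1. The values used here are those the authors deposited in the value table of the whole series, 1 linear intensity per probe and array for 45281 probes. Background subtraction, scaling and filters are not given in the sources used here. The values themselves show neither a subtraction nor a scaling, since the most frequent intensity lay between 99.2 and 108 on every array and the upper quartiles ranged from 146 to 188. Scanner files, detection p-values and bead counts were not used here.

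Groups came from the sample labels, which give 2 arrays of BXD2 mice given PBS, 1 array of BXD2-Ifnar-/- mice given PBS and 1 array of BXD2 mice given sLTβR-Fc. Each array holds cells of 2 mice, 8 mice in all if no mouse was used for more than 1 array. The labels give the control arrays as separate samples without saying whether their mice differed, so p-values measure only the spread between these 2 arrays, which may be technical. Scan dates and slide positions were not used here.

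Genes were named through the platform's annotation table, in which 34885 probes have 1 gene symbol, 18 have several and 10378 have none. Of 19057 symbols, 18992 were found by gene identifier in the mouse reference table, all under the same symbol. Probes without exactly 1 symbol were left out of the comparisons. Each gene was represented by its probe with the highest mean over the 4 arrays (8113 of the genes compared have further probes), and where further probes disagree the text says so, giving the median of them where a gene has several. Some genes and lists of interest are not reported here.

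The background of each array was taken as the most frequent intensity, with a spread from the values below it mirrored about it, and a probe counted as above background when it passed the 95% point of that noise. The limits were 114, 116, 106 and 109, and 52.9%, 52.7%, 52.1% and 51.4% of probes passed in control 1, control 2, Ifnar-/- and sLTβR-Fc. Values were quantile normalised between arrays, raised to a floor of 111 (the mean of the limits) and converted to log2. Genes above background on at least 1 array, 14497 of them, were kept. A log2 difference given in the text is on this scale and understates the change of dim genes, because background remains in the values. A gene that was not above background on a whole group has only a bound, written as at least so many fold, computed against the lowest signal counted as above background.

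The plan written before the data were examined was to leave the values unscaled if the array medians lay within 10% of each other. They did (107 to 117), but these medians measure background, as close to 50% of the probes are not above it, while the brighter probes differed between arrays. Quantile normalisation was therefore used as the main setting, a departure from that plan made after seeing the values, and the values as deposited were kept as an alternative. As deposited, the median of all genes was -0.099 on the Ifnar-/- array and -0.19 on the sLTβR-Fc array, and it was 0.16 on the sLTβR-Fc array under median scaling.

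Groups were compared in limma 3.58.1 (R 4.3.3) with 1 fit of 3 group means over the 4 arrays and eBayes with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method to 0.05. The fit has 1 residual degree of freedom, from the control pair, and the lone arrays are assumed to vary as the controls do. An SE in the text comes from this fit. It rests on the gap between the control arrays and holds no spread of the lone array's group. Where the control values happened to lie close together the SE is small and can look too precise. In this fit 1151 genes had no spread between the controls, nearly all at the floor on both, and the prior weight on the shared variance was low (0.972 degrees of freedom, against 13.5 without the genes at the floor). In simulations with 200 genes changed this fit recovered 0% of genes changed by a log2 of 1, 2 or 3. A fit limited to the 10693 genes above background on all 4 arrays, written down beforehand as a variation, had a prior of 881 degrees of freedom. In 20 simulations on those genes it recovered 49.3% (Ifnar-/- comparison) and 48.1% (sLTβR-Fc comparison) of genes changed by a log2 of 1, and 98.6% and 98.0% at a log2 of 2, and called 0 genes on unchanged arrays. Its calls rest on the same control pair, and it was put beside the first fit in the text only after that fit had called 0 genes. A rule of size that needs no test, also fixed beforehand, leads the text for the same reason, a gene counting when its log2 difference from each control array was at least 1 in the same direction. In simulations it recovered 33.6% and 30.1% of genes changed by a log2 of 1, which is the rule's own threshold, and 99.6% and 99.7% at a log2 of 2. All simulated changes were increases, so none of these shares covers lower genes. For this rule and the first fit the changed genes had a control mean above 2 times the floor, so the shares do not cover dimmer genes. In all these simulations every array, lone or control, drew its noise gene by gene from the control pair at like brightness. They hold no difference between pools beyond that pair, so they cannot show how many false calls such a difference would give.

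Before the data were examined, 36 gene lists with 841 entries were fixed for pathways of the study, macrophage functions and the other cell types that a spleen sort could hold; 757 entries were on the array and 711 above background. For each list the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, a description and not a p-value, and the same median was computed between the control arrays. limma's fry gave a directional p for each list, adjusted over lists, which asks whether a list's genes moved on balance 1 way and does not compare them with other genes. Lists of eosinophil and of pancreatic acinar genes were added after the values had been seen. For the pair of comparisons, 100 simulated sets of unchanged arrays against the same controls gave the correlation and covariance that shared controls alone produce.

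Genes named in the text follow a rule fixed before the data were examined: the targets of the study and the genes of the sort gate; the 10 genes in each direction ranked by the smaller of the 2 differences from the control arrays; up to 4 members per list and comparison ranked the same way; and, between the lone arrays, the 5 genes in each direction farthest apart with the control mean between them. Predicted genes, clone names and antigen receptor segments were passed over. The genes given as examples of those 2-fold from the controls on both lone arrays were chosen after their values were seen. Alternatives covered the scaling, the floor, the filter, the choice of probe, the variance prior, the arrays in the fit, the size threshold, leaving out each control array, list means and lists without shared members, plus 3 added after seeing the data: values as deposited, normexp background correction with an offset of 50, and a fit without the genes at the floor on both controls.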

Results

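Gene expression was measured in marginal zone macrophages of the spleen, phagocytic cells that sit at the border of the lymphoid white pulp and the blood-filtering red pulp. The mice were BXD2, a recombinant inbred strain that develops a lupus-like autoimmune disease with age. Per the labels, the cells had been sorted for low CD11b, no F4/80, no I-Ab and surface SIGN-R1. There were 4 single-colour bead arrays, each from the cells of 2 mice aged 2.5 months. A pair of arrays came from BXD2 mice given PBS (the controls), 1 from BXD2 mice lacking the type I interferon receptor and given PBS (Ifnar-/-), and 1 from BXD2 mice given 25 µg sLTβR-Fc, a soluble decoy receptor that binds lymphotoxin. All mice were killed 10 hours after the injection. The comparisons ask how loss of interferon signalling and blockade of the lymphotoxin β receptor change the macrophages, which the submitters describe as already defective in BXD2 mice, restored without the receptor and further impaired by the decoy.

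Between 23288 and 23940 of the 45281 probes lay above the background of their array, and 14497 genes above background on at least 1 array were compared. The upper quartile of the deposited intensities was 188 and 179 on the control arrays, 156 on the Ifnar-/- array and 146 on the sLTβR-Fc array. After normalisation the control arrays correlated at r = 0.993 across genes, which are not independent replicates, and 31 genes stood 2-fold or more apart between them. Any other pair of arrays had between 276 and 424 such genes. The Ifnar-/- array and the sLTβR-Fc array have no replicate, so each was set against both control arrays, and a gene is called 2-fold higher or lower here only where it differed that much from each of them. The number of arrays limits the precision throughout, and because the intensities contain background, differences of dim genes are understated.

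The receptor and ligand genes of the 2 pathways were measured first. Ifnar1, a chain of the type I interferon receptor, read 157 and 149 on the control arrays, 191 on the Ifnar-/- array and 117 on the sLTβR-Fc array. Where its probe lies relative to the disrupted part of the gene is not given in the sources used here, so this value does not check the genotype. Ifnar2, the other chain, read 309 and 351 on the controls, 248 on the Ifnar-/- array and 235 on the sLTβR-Fc array, while its further probes lay at a median log2 difference of 0.10 and -0.11. Ltbr, the receptor that the decoy imitates, was not above background on either control array and read 128 and 128 on the Ifnar-/- and sLTβR-Fc arrays, at least 1.16-fold and 1.15-fold higher. Its ligand genes Ltb and Tnfsf14 read 404 and 483 and 946 and 926 on the controls, 537 and 932 on the Ifnar-/- array, and 413 and 678 on the sLTβR-Fc array. Lta, the third ligand gene, read 576 and 478 on the controls, 865 on the Ifnar-/- array and 622 on the sLTβR-Fc array.

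The genes of the sort gate were measured too. Cd209b, which encodes SIGN-R1, read 127 and 130.1 on the control arrays and 152 and 145 on the Ifnar-/- and sLTβR-Fc arrays, after normalisation. Its deposited values on the controls were 1.17 times their background limits. Further Cd209b probes lay below the limits on both controls. As deposited they were 1.47 and 1.12 times the limit on the Ifnar-/- array and 1.00 and 0.98 times on the sLTβR-Fc array. H2-Ab1, which encodes the I-A β chain that the gate excluded, read 8662 and 8305 on the controls, 16289 on the Ifnar-/- array and 9488 on the sLTβR-Fc array. Adgre1, which encodes F4/80, differed between the controls (629 and 306) and read 1017 on the Ifnar-/- array and 631 on the sLTβR-Fc array. Itgam, which encodes CD11b, stayed between 111 and 118 on the 4 arrays. Marco, a scavenger receptor of these macrophages, read 252 and 162 on the controls, 181 on the Ifnar-/- array and 168 on the sLTβR-Fc array.

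Interferon-stimulated genes were lower on the Ifnar-/- array. Of 43 measured members, 29 lay below both control arrays and 4 above both, 7 of them 2-fold lower, and the list's median log2 difference from the control mean was -0.31, below all 10000 random lists matched on expression. Under the other settings tried this median ranged from -0.59 (values as deposited) to -0.066 (a doubled floor). Ifi27, which is not on the list but among the lowest genes of this array, read 5719 and 6621 on the controls and 1123 on the Ifnar-/- array (log2 -2.45 ± 0.15, SE), and its further probe gave -2.28. Ifi27l2a, a relative of it, read 646 against 2432 and 3119 (log2 -2.09 ± 0.23) and Cmpk2, a mitochondrial nucleotide kinase, 196 against 680.5 and 617 (log2 -1.73 ± 0.12). The brightest probes of the antiviral oligoadenylate synthetase family genes Oas1g and Oasl2 were lower by a similar size (log2 -2.01 and -2.06), but further probes of these genes lay at -0.0026 and -0.12. Between the controls the list differed by 0.16, control 2 being higher, and this was above all matched random lists. A place outside the random lists therefore does not by itself separate genotype from a difference between arrays for this list. None of its members passed limma's adjusted threshold over all genes or adjusted over the list alone, and 18 of 35 passed as lower in the fit restricted to genes above background on every array. On the same array neutrophil markers lay at a median of -0.81 and B cell markers at 0.58.

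Genes of antigen presentation by MHC class II were higher on the Ifnar-/- array. Of 11 measured members 10 lay above both controls, the median log2 difference was 0.74, above all matched random lists, and 9 passed limma adjusted over the list alone, against 0 over all genes. H2-DMb1 and H2-DMa, which load peptides onto class II molecules, were 2.28-fold and 2.01-fold the control mean (log2 1.19 ± 0.21 and 1.01 ± 0.12), and H2-Eb1 and H2-Ab1, which encode β chains of the surface molecules, 1.94-fold and 1.92-fold. B cell markers moved with them, 15 of 16 above both controls at a median of 0.58, among them Blk, a B cell kinase (log2 0.73), and Spib, a B cell transcription factor (log2 1.04, though -0.015 on further probes). Dendritic cell markers did so too, 13 of 16 at a median of 0.40 and 6 adjusted over the list alone, 1 of them at the floor on both controls. Batf3, a transcription factor of cross-presenting dendritic cells, was 2.52-fold and Itgax, which encodes CD11c, 2.38-fold the control mean. Their further probes lay at log2 0.33 and 0.090. Between the controls these 3 lists differed by -0.061, -0.098 and -0.033.

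Cell cycle genes were lower on the Ifnar-/- array, 28 of 30 below both controls with a median log2 difference of -0.52. Plk1, a mitotic kinase, read 432 against 1352 and 1158 on the controls (log2 -1.54 ± 0.15). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, lay at log2 -1.49 ± 0.18 and -1.36 ± 0.21, and Cdc20, an activator of the anaphase-promoting complex, at -0.98 ± 0.065. The count adjusted over the list alone was 13 and over all genes 0. In limma's directional fry test the list had an adjusted p of 0.0603, the lowest of any list in this comparison, where interferon-stimulated, MHC class II and neutrophil lists had adjusted p values of 0.413, 0.236 and 0.646. On the sLTβR-Fc array the lowest was 0.224, for eosinophil markers. Between the controls the list's median was 0, with members on either side.

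Markers of neutrophils, red cell precursors and T cells were also lower on the Ifnar-/- array. Neutrophil markers had a median of -0.81 with 18 of 22 below both controls, and the granule protein genes Ltf and Camp read 215 and 197 against 2811 and 1617 and 2641 and 1324. Retnlg, a resistin-like gene on the same list, was higher instead, at 1286 against 299.8 and 268 (log2 2.18 ± 0.13). Erythroid markers had a median of -0.82, with Klf1, a transcription factor of red cell precursors, at log2 -1.41 ± 0.22. The control arrays stood apart on these lists as well, control 2 minus control 1 being -0.39 for neutrophil and -0.56 for erythroid markers. T cell markers had a median of -0.29, 14 of 18 below both controls, including Cd3d of the T cell receptor complex (log2 -0.98 ± 0.23). NK cell markers had a median of 0.60, and the controls differed on them by 0.54.

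Genes of the lymphotoxin β receptor and noncanonical NF-κB pathway had a median of 0.30 on the Ifnar-/- array (0.058 in the values as deposited), above the central 95% of matched random lists, with 16 of 23 above both controls and 1 adjusted over the list alone, Ltbr, which was at the floor on both controls. Relb, the transcription factor of that pathway, was 1.93-fold and Tnfaip3, an NF-κB feedback inhibitor, 2.01-fold the control mean. The brightest probe of the adhesion gene Vcam1, whose controls read 1344 and 486, read 235. B cell and dendritic cell markers had medians of 0.58 and 0.40 on the same array. Cytoskeletal targets of MRTF and SRF had a median of 0.031, within the range of matched random lists. Their member Myh9, nonmuscle myosin heavy chain, was among the lowest of all genes on its brightest probe (log2 -2.84 ± 0.082), but 0.64 on its further probes. Marginal zone macrophage genes had a median of 0.079 and apoptotic cell clearance genes of 0.086, both within the matched range. Between the controls they differed by -0.21 and -0.16, both below all matched random lists. In the values as deposited these medians were -0.044 and -0.089. The iron exporter Slc40a1 read 562 against 2914 and 1594 on the controls, and the clearance receptor Axl 238 against 1016 and 436.

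In all, 83 genes were 2-fold higher and 137 were 2-fold lower on the Ifnar-/- array than on both controls. In the values as deposited, without scaling between arrays, these counts were 30 and 295. Simulated unchanged arrays gave a mean of 5.55 such genes and at most 14. The simulated control pairs had a mean of 22.05 genes 2-fold apart and at most 28, against 31 in the data. Genes also vary independently in these simulations, so this background may be too low. The highest places outside the lists above went to Cd209d, a C-type lectin of the SIGN-R family (216 and 306 against 1304, log2 2.34 ± 0.32), Apol7c, an apolipoprotein L gene (3.69-fold), the linker histone gene H1f2 (3.62-fold), Upp1, uridine phosphorylase (3.20-fold), Ccnd1, cyclin D1 (3.17-fold) and the cytochrome Cyp4f16 (3.03-fold). The acinar enzyme genes Pnliprp1, Prss2 and Cela2a, made by the exocrine pancreas, were 4.27-fold, 3.80-fold and 5.49-fold the control mean. The remaining lowest places went to Rif1, Cap1, Sphk1 and Gnas, with log2 differences of -2.47, -2.32, -2.03 and -1.97 on their brightest probes. Further probes of Rif1, Sphk1 and Gnas lay at -0.33, 0.042 and 0.15. Among 125 genes on this 2-fold list with a further probe, the median of the further probes had the same sign in 105 and at least 50% of the size in 38. Dim probes, which the floor holds near 0, are included in that count.

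limma with Benjamini-Hochberg adjustment called 0 of 14497 genes in this comparison (lowest adjusted p 0.216), with 2853 at an unadjusted p under 0.05, against a mean of 1162 on simulated unchanged arrays. In the fit restricted to the 10693 genes above background on every array it called 978 higher and 1017 lower. Both fits take the spread from the control pair alone and assume that the lone array varies as they do.

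**Figure D1:**
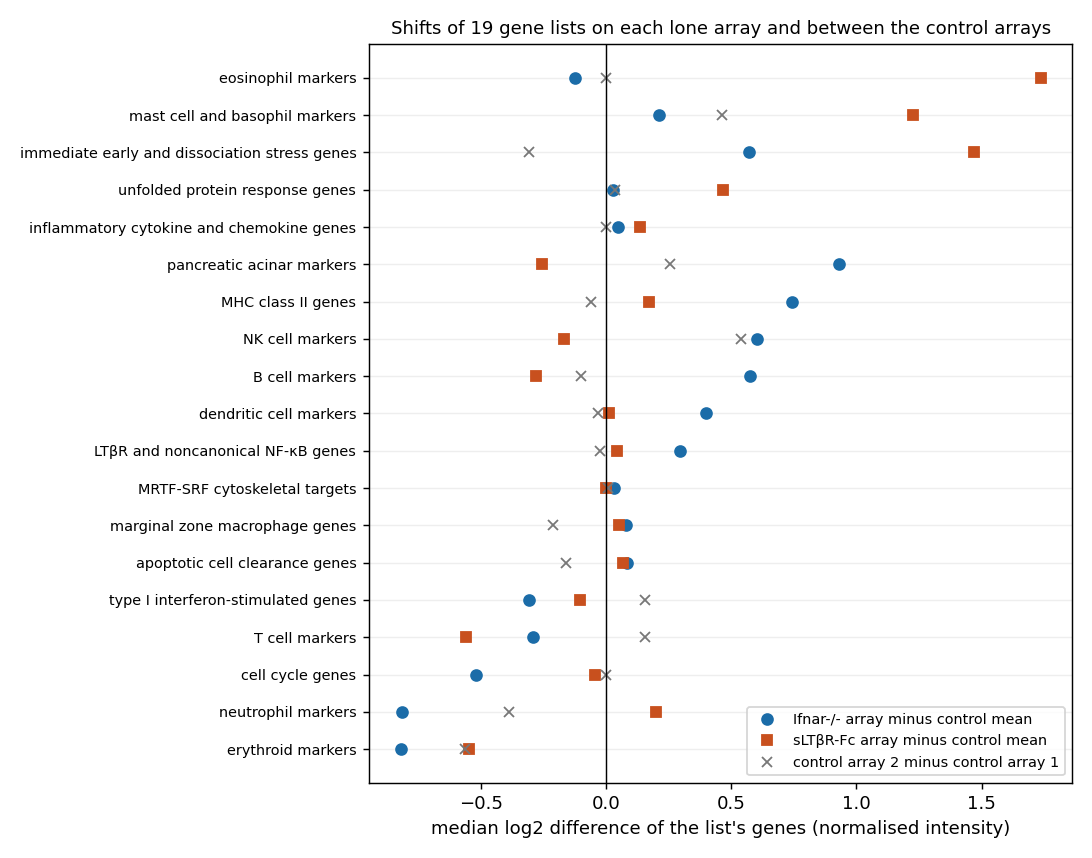
Median log2 difference of the normalised intensities (horizontal axis) for 19 gene lists (vertical axis). Circles give the Ifnar-/- array and squares the sLTβR-Fc array against the mean of the control arrays, and crosses give control array 2 against control array 1. Eosinophil markers on the sLTβR-Fc array lie farthest to the right at 1.74, and erythroid markers, at -0.82 on the Ifnar-/- array, also differ by -0.56 between the controls.

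The sLTβR-Fc array was compared with the same controls. These were given PBS, and no array came from mice given a control Fc protein. Blockade of the lymphotoxin β receptor therefore cannot be told apart from other effects of injecting the protein. Eosinophil genes stood highest on the sLTβR-Fc array. This list was drawn up after the values had been seen, and 10 of its 11 measured members lay above both controls, 8 of them 2-fold, at a median log2 difference of 1.74. Ear6, an eosinophil-associated ribonuclease gene, read 3335 against 380 and 422 (log2 3.06 ± 0.12), eosinophil peroxidase Epx 3474 against 426 and 549.8, and the granule protein genes Prg3 and Prg2 1568 and 19445 against 253 and 266 and 3917 and 4419. The Ear genes are close relatives, and their probes may not tell them apart. Mast cell and basophil markers, fixed beforehand, were all above both controls (10 of 10, median 1.23, 0 adjusted over the list alone). Among them Cpa3, mast cell carboxypeptidase, was 3.87-fold and Prss34, a basophil protease, 3.52-fold the control mean. The neutrophil elastase gene Elane and its neighbour in the azurophil granule Prtn3 were 5.69-fold and 3.68-fold, while the whole neutrophil list had a median of 0.20 and differed by -0.39 between the controls. Its median was -0.16 in the values as deposited and -0.00043 without control 2. The controls differed by 0.47 on the mast cell and basophil list and by a median of 0 on the eosinophil list.

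Immediate early genes were higher as well, 21 of 27 above both controls and 15 of them 2-fold, at a median of 1.47. The list holds genes that also respond to tissue dissociation. 6 members passed adjusted over the list alone and 0 over all genes. The stress-induced gene Ier3 was 6.10-fold, the stress transcription factor Atf3 5.25-fold and the AP-1 member Fosb 6.33-fold the control mean. The heat shock gene Hspa1a read 4248 against 811 and 204, with 0.22 on its further probe. The same list had a median of 0.57 on the Ifnar-/- array and of -0.30 between the controls. The interleukin gene Il6 read 1460.1 against 162 and 216 (log2 2.97 ± 0.27), and the chemokine genes Ccl3 and Ccl4 were 4.59-fold and 3.41-fold. Inflammatory cytokine and chemokine genes as a list had a median of 0.14 with 5 of 26 members 2-fold higher, and -0.0080 in the values as deposited, where the median of all genes was -0.19.

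Genes of the unfolded protein response had a median of 0.47 on the sLTβR-Fc array, with 15 of 20 above both controls and 3 adjusted over the list alone, Asns among them as lower. In the deposited values it was -0.033, again above the median of all genes. Chac1, which degrades glutathione, was 2.72-fold, and Dnajb9 and Ddit3, a chaperone partner and a stress transcription factor, were each 2.03-fold the control mean, while Asns, asparagine synthetase, was lower (log2 -0.87 ± 0.063). Stromal and endothelial markers had a median of 0.27 on the same array (-0.065 as deposited) and monocyte markers of 0.20 (-0.049 as deposited).

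T cell and B cell markers were lower on the sLTβR-Fc array, while NK cell markers, at a median of -0.17, lay within the matched range. 17 of 18 T cell markers lay below both controls at a median of -0.56, with Lat, the T cell adaptor, at log2 -1.06 ± 0.13 and Cd3g at -1.07 ± 0.20. Of 16 B cell markers 13 did so at a median of -0.28, with the complement receptor gene Cr2 at 456 against 1007 and 845 on its brightest probe (0 on a further probe, log2) and the scaffold gene Bank1 at 837 against 2452 and 1748. None passed limma over all genes or adjusted over either list alone, and 11 of 16 T cell and 6 of 16 B cell markers passed as lower in the restricted fit. Between the controls T cell markers differed by 0.16 and B cell markers by -0.098. Erythroid markers had a median of -0.54, against -0.56 between the controls.

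The receptor's own pathway lay near 0 as a list. Lymphotoxin β receptor and noncanonical NF-κB genes had a median of 0.045 on the sLTβR-Fc array, within the range of matched random lists, with 10 of 23 above both controls and 5 below. The sign turned to -0.087 under median scaling and -0.53 in the values as deposited. The NF-κB feedback genes Tnfaip3 and Nfkbia lay at log2 1.61 and 0.72. The 2 members that passed adjusted over the list alone, Cxcl13 and Ltbr, lay at or next to the floor on both controls, so their small spread there carries little weight. Traf2, an adaptor of the receptor, was not above background on the sLTβR-Fc array and at least 1.59-fold lower there. Targets of MRTF and SRF had a median of 0. Marginal zone macrophage genes had a median of 0.053, with the cytokine gene Il10 at 209.9 against 139.5 and 136, and apoptotic cell clearance genes of 0.069, with the scavenger receptor Stab1 at 943 against 488 and 360.5. Interferon-stimulated genes had a median of -0.10 on this array, below the central 95% of matched random lists, with 19 of 43 below both controls, and 7 of 35 passed as lower in the restricted fit. In the values as deposited the marginal zone macrophage and clearance medians were -0.11 and -0.13.

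Altogether 148 genes were 2-fold higher and 68 were 2-fold lower on the sLTβR-Fc array than on both controls. This split depends on the scaling, since median scaling gave 99 and 122 and the values as deposited 34 and 650. Simulated unchanged arrays gave a mean of 5.6 such genes and at most 9, a background that may be too low here as well. The lowest places went to the pancreatic amylase gene Amy2a5 (2513 and 6416 against 129) and Cela2a (not above background, at least 5.19-fold lower). Next came Ms4a4b, a lymphocyte membrane protein gene (log2 -2.29), Smchd1, a chromatin protein gene (log2 -1.62), and Gimap9, a lymphocyte GTPase gene (log2 -1.56). The SEs of Ms4a4b and Gimap9 were 0.077 and 0.062 in the main fit, but 0.20 and 0.19 in the restricted fit. Rif1, Sphk1, Crebl2, Myh9 and Kdm5a followed with log2 differences between -1.72 and -1.52 on their brightest probes. The medians of their further probes, dim ones included, lay between -0.32 and 0.41. Further probes at 2 times the floor or more on the controls lay at -0.69 for Kdm5a and 0.86 for Myh9. Among 106 genes on this 2-fold list with a further probe, the median of the further probes, dim ones included, had the same sign in 88 and at least 50% of the size in 25.

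limma called 0 genes (lowest adjusted p 0.159), with 3388 at an unadjusted p under 0.05, against a mean of 1158 on simulated unchanged arrays. In the fit restricted to genes above background on every array it called 1421 higher and 991 lower. As before, the lone array is assumed to vary as the controls do.

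**Figure D2:**
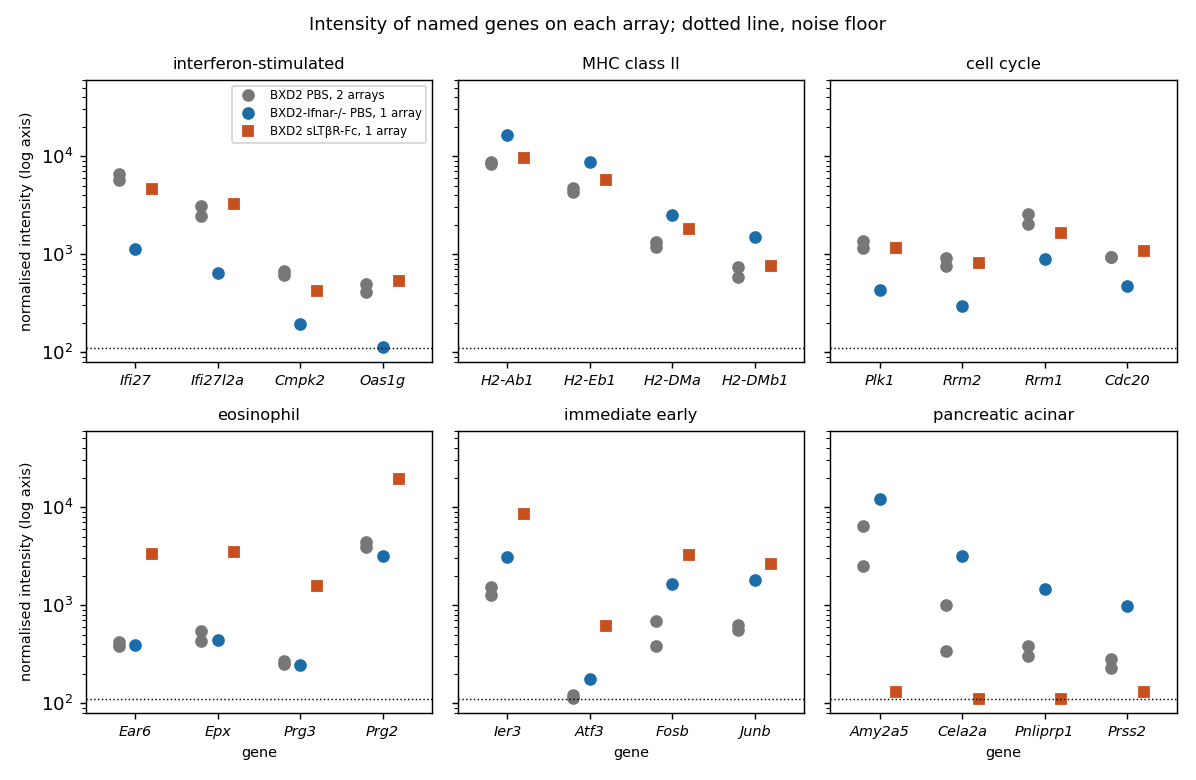
Normalised intensity on a log axis (vertical) for 4 named genes of each of 6 groups (horizontal), with grey circles for the control arrays, blue circles for the Ifnar-/- array, orange squares for the sLTβR-Fc array and a dotted line at the noise floor of 111. The interferon-stimulated genes, with Ifi27 added from outside the list, lie lowest on the Ifnar-/- array, Ifi27l2a at 646, and the eosinophil genes highest on the sLTβR-Fc array, with Prg2 at 19445.

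The arrays that the submitters describe as restored and as further impaired were then set against each other, which involves both a genotype and an injection. Eosinophil, neutrophil and unfolded protein response lists were lower on the Ifnar-/- array than on the sLTβR-Fc array, with median log2 differences of -1.91, -1.70 and -0.47, and so were cell cycle genes at -0.55. B cell, MHC class II and dendritic cell lists were higher, at 0.85, 0.56 and 0.41. Genes of the lymphotoxin β receptor pathway lay at 0.19, above the central 95% of matched random lists. The genes farthest apart with the control mean between them were Amy2a5, Cela2a, Pnliprp1, Prss2 and the chymotrypsin-like gene Ctrl on the higher side, all pancreatic. On the lower side they were Elane, Ltf, Prss34, Ear6 and Prtn3, all genes of granulocytes, with log2 differences of -3.37, -3.32, -3.31, -3.08 and -3.04. limma called 0 genes (lowest adjusted p 0.183), with 3081 at an unadjusted p under 0.05, and 1714 in the restricted fit.

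Genes that stood apart from the controls on both lone arrays mostly did so in the same direction. 16 genes were 2-fold higher on both arrays and 34 were 2-fold lower on both, and 5 went opposite ways. In any of 100 simulations of unchanged arrays against the same controls, at most 1 gene was higher on both and at most 1 lower on both. Those simulations vary each gene on its own, so they hold no shift common to the genes of a cell type. The 16 included the immediate early genes Fosb, Junb, Dusp1, Zfp36 and Ier3, together with Il6, H1f2, Upp1 and the galectin gene Lgals3. The 34 included, on their brightest probes, Rif1, Sphk1, Myh9 and Ms4a4b and the erythroid genes Klf1, Rhd and Car2. Of 14 further probes, measured on the controls at 2 times the floor or more and covering 10 of the 34 genes, 12 were lower on both arrays. The other 2 were higher on both, a Myh9 probe at log2 1.00 and 0.86 and a Snrnp70 probe at 0.25 and 0.077. The median log2 difference of the 14 was -0.66 on the Ifnar-/- array and -0.75 on the sLTβR-Fc array. The brightest probes of these genes had -1.69 and -1.41. Across genes the differences correlated at r = 0.415 with a covariance of 0.0493, against 0.334 and 0.00853 for simulated unchanged arrays, which share the same controls. With a separate control array for each comparison, r was 0.245 or 0.406 and the covariance 0.0330 or 0.0484. Part of the sharing may come from the shared controls.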

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

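All 9 tests of explanations in this part were chosen after the values had been seen, and the pair on immediate early genes was chosen last, after the pair on genes lower on both lone arrays had settled nothing.

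Probes without exactly 1 gene symbol are outside the comparisons above, and 5551 of them lay above background on at least 1 array. On the Ifnar-/- array 62 of these stood 2-fold or more from both controls (11 higher, 51 lower) and on the sLTβR-Fc array 50 did (23 higher, 27 lower), against 6 between the control arrays.

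Transcripts of pancreatic acinar cells differed widely between the arrays. Amy2a5 read 2513 and 6416 on the controls, 12153 on the Ifnar-/- array and 129 on the sLTβR-Fc array, and Cela2a read 337 and 995, 3178 and the floor. Genotype or injection alone would leave the control arrays alike, but the list's median differed by 0.25 between them, a gap that neither can account for. The list was added after the values had been seen, so its place above all matched random lists there is not a test. An effect of genotype or injection on the lone arrays stays open. Carry-over of pancreatic RNA, an organ that lies against the spleen, in differing amounts would keep the enzymes in 1 order over the arrays. The order Ifnar-/-, control 2, control 1, sLTβR-Fc was shared by 20 of 23 measured markers, but this order and the list were drawn from the same values and 12 markers sat at the floor on the sLTβR-Fc array, so the count does not test carry-over, which stays open.

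Marker lists of other cell types moved in opposite directions, with the gate gene Cd209b near background and H2-Ab1, which the gate excluded, at 8305 or more on every array. A lower share of the sorted macrophages on the Ifnar-/- array would raise all other cell types alike, but 3 of 14 marker lists lay above and 5 below the central 95% of matched random lists. A cell mixture that differs from pool to pool would also show between the controls, and 8 of the 14 lists were outside that range there, where 0.7 are expected if genes of a list vary independently. A cell mixture differing from pool to pool may account for part of the shifts. An effect of genotype or injection on the cell types cannot be told apart from it, since each of those groups has 1 array.

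Immediate early genes were higher on both lone arrays. The Ifnar-/- array, from mice given PBS and so without the sLTβR-Fc injection, had a median of 0.57. The pattern was named from this value, so it does not test whether the injection alone is the cause on the sLTβR-Fc array. Handling that differs from pool to pool could account for shifts on any array, and the controls differed by -0.30 on this list, below all matched random lists. Handling and a response to each condition stay open for both arrays. The injection stays open for the sLTβR-Fc array alone, and the larger median of 1.47 there has no replicate.

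The 34 genes 2-fold below the controls on both lone arrays were looked at for causes in the measurement. Signal of single probes rather than of the whole transcript would leave further probes of the same genes nearly unshifted. Their median was -0.66 on the Ifnar-/- array and -0.75 on the sLTβR-Fc array, 0.390 and 0.531 of the shift of the brightest probes. The limit against this cause, 50% of that shift on both arrays, was thus met on the sLTβR-Fc array alone. Of the 14 further probes, which cover 10 of the genes, 12 were lower on both arrays. Dimness of the lone arrays left over after scaling would remove most of the genes under other scalings. Of the 34 genes, 33 stayed under median scaling, 34 under normexp with quantile scaling and 29 under cyclic loess, the last short of the 90% set for ruling this out. All 34 also stayed in the values as deposited, which are not scaled and so leave any dimness in place. Each cause could act on some of these genes, but the tests rule out neither for all of them.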

How the results depend on the processing

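Values as deposited, normexp and the fit without floor genes were chosen after seeing the data. The direction of the interferon-stimulated genes on the Ifnar-/- array held throughout (list median -0.59 to -0.066 over 13 settings). The covariance of the 2 comparisons stayed positive (0.0291 to 0.0804). Shared controls alone make it positive, at 0.00785 to 0.00920 for simulated unchanged arrays, so its sign says little in the settings that share them. With a separate control array for each comparison it was 0.0330 or 0.0484. Of 5616 values of named genes under alternatives 5367 kept their direction, and of 1440 list values 1259 did. The arrays' number and the dim probes, whose values are mostly background, set the limit. Where no cause is named, the cause was not tested. No paired analysis was run, because the labels used here give no pairing of arrays and the Ifnar-/- and sLTβR-Fc groups have 1 array each.

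limma's count of 0 (Ifnar-/-, sLTβR-Fc, and Ifnar-/- against sLTβR-Fc) became 1995, 2412 and 1714 for genes above background on all 4 arrays, 1359, 1798 and 1099 without genes at the floor on both controls, 1741, 1588 and 1386 with a doubled floor, 1949, 2162 and 1487 with an offset of 50, 1968, 2182 and 1494 with normexp, 619, 790 and 1140 with no filter, and 2452, 5579 and 4848 under median scaling. It stayed 0 under cyclic loess, the mean of all probes, no trend, a robust prior and the values as deposited, and for the Ifnar-/- and sLTβR-Fc comparisons under the 3 arrays of a comparison alone. Of the Ifnar-/- calls 2027 of 2452 under median scaling and 552 of 619 with no filter were genes without any spread between the controls, so these counts say little, and with a doubled floor 57.6% of all genes had none. Leaving out a control array leaves no residual degree of freedom and so no test.

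Genes 2-fold higher and lower (83 and 137 on the Ifnar-/- array, 148 and 68 on the sLTβR-Fc array) became 47, 53, 98 and 28 with the mean of all probes, 11, 48, 45 and 7 at a log2 of 1.5, and 30, 295, 34 and 650 as deposited, where all 137 and all 68 lower genes of the main setting were kept. Median scaling gave 122 lower genes on the sLTβR-Fc array. Without 1 control array, and so with a single difference to pass, the counts ranged from 113 to 163 and 163 to 261 on the Ifnar-/- array, the higher ones without control 2, and from 196 to 215 and 107 to 149 on the sLTβR-Fc array.

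The covariance was 0.0291 with the mean of all probes and 0.0804 as deposited, and 0.0465 to 0.0693 without 1 control. The interferon list's median on the Ifnar-/- array was -0.066 with a doubled floor, which removes dim differences, -0.59 as deposited, and -0.55 as a mean; without 1 control it ranged from -0.33 to -0.23. The lymphotoxin receptor list on the sLTβR-Fc array (0.045) was -0.087 under median scaling, 0 with a doubled floor, 0.11 as a mean, -0.53 as deposited, and 0.024 to 0.097 without 1 control. As deposited 36 of 111 list medians had the opposite sign. Of 29 against the controls, 20 kept their sign relative to the median of all genes. Most genes are dim, so that median does not remove the lower level of bright probes on the unscaled arrays. The count therefore cannot tell whether this lower level accounts for the remaining sign changes. Among these, MHC class II genes on the sLTβR-Fc array, which are bright, went from 0.167 to -0.272 relative to all genes. With list means 14 differed in sign and under median scaling 10, and 54 became 0 with a doubled floor. Among genes 2-fold from the controls and lists outside the central 95% of matched random lists, signs reversed for Gnas on the Ifnar-/- array with the mean of all probes (log2 0.0090) and, as deposited, on the sLTβR-Fc array, for inflammatory (-0.0080), monocyte (-0.049), neutrophil (-0.16), stromal (-0.065) and unfolded protein response lists (-0.033). Relative to the median of all genes on that array (-0.19) these 5 lists stayed above 0, at 0.18, 0.14, 0.034, 0.13 and 0.16. Without control 2, whose neutrophil markers were the lower of the pair, the neutrophil list on the sLTβR-Fc array was -0.00043, and 0.52 without control 1.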

Other observations

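No test was added for this part, and what to describe in it was chosen after the values had been seen. Genes of B cell receptor and BAFF receptor signalling had a median log2 difference of 0.32 on the Ifnar-/- array, with 9 of 13 members above both controls, and of -0.012 on the sLTβR-Fc array. In the values as deposited these medians were 0.0052 and -0.60. The kinase genes Syk and Btk were 2.24-fold and 1.55-fold the control mean on the Ifnar-/- array, and the BAFF-binding receptor gene Tnfrsf13b 1.82-fold, with log2 -0.50 on its further probes. B cell markers had a median of 0.58 on the same array. Toll-like receptor and sensing genes had a median of 0.16 there, within the matched range, with the transcription factor Irf5 at log2 0.89 ± 0.071 and the receptor trafficking gene Unc93b1 at 0.91 ± 0.12. On the inhibitory side the checkpoint genes Havcr2 and Cd274 were 1.92-fold and 1.79-fold the control mean, and Il10ra 1.77-fold, while the ectonucleotidase gene Nt5e was lower on both lone arrays (log2 -1.03 and -1.06). The immunoregulatory list as a whole had a median of 0.085 on the Ifnar-/- array and 0.018 on the sLTβR-Fc array, the latter -0.11 in the values as deposited, where toll-like receptor and sensing genes lay at -0.015 on the Ifnar-/- array.

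Of the metabolic lists, glycolysis and hypoxia genes had a median of 0.13 on the sLTβR-Fc array and -0.056 on the Ifnar-/- array, with Vegfa, an angiogenic factor, 2.43-fold and the oxygen sensor Egln3 2.18-fold the control mean on the sLTβR-Fc array. In the values as deposited this list's median on the sLTβR-Fc array was -0.14, and that of LXR targets on the Ifnar-/- array -0.11. LXR target and lipid efflux genes lay at 0.055 and -0.063 on the Ifnar-/- and sLTβR-Fc arrays and cholesterol synthesis genes at -0.0032 and -0.040. Ribosomal protein genes lay at -0.022 and -0.067. The desaturase gene Scd1 was 1.86-fold the control mean on the Ifnar-/- array. In the fit restricted to genes above background on every array, Scd1 passed on the Ifnar-/- array and Vegfa and Egln3 on the sLTβR-Fc array.

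Red pulp macrophage markers, of cells that recycle iron, had a median of -0.16 on the Ifnar-/- array and -0.10 on the sLTβR-Fc array, and -0.25 between the controls. Vcam1 read 1344 and 486 on the controls, Slc40a1 2914 and 1594, Axl 1016 and 436 and Cd163 493 and 222, each higher on control 1. On the Ifnar-/- array these genes read 235, 562, 238 and 194, below both controls. Of the list's 15 genes, 8 lay below both controls on that array and 5 above both. The median of the list differed more between the controls than between either lone array and the control mean.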
